A study of Arabidopsis thaliana with 6 samples.

How the data were processed

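Total RNA from inflorescence apices of Arabidopsis thaliana was compared between 3 mock-treated and 3 dexamethasone-treated samples. Dexamethasone, a synthetic glucocorticoid, switched on AP2m3, a form of the flower and meristem regulator APETALA2 (AP2) that escapes the microRNA miR172. Per the labels, plants grew at 21 °C with 16 h of light and 8 h of dark. They were treated 2 weeks after bolting, and the apices were collected 6 to 8 h later with the visible flower primordia removed. Per the labels' protocols, RNA was extracted with a silica column kit and libraries were made with a stranded poly(A) kit.

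The deposited values are raw counts of reads per gene locus, not normalized, and the name of the deposited table says that HTSeq counted them. TopHat, Bowtie, RSEM and Cufflinks are named without versions or roles in the submitters' processing notes. The genome build, the annotation release, the strand setting and any read filter are not given in the sources used here. The table held 28775 loci and 3 blank lines, which hold no gene and no counts. Its columns are headed CT and Dx. CT columns were taken as mock, because mock is the other group besides dexamethasone in the labels, and Dx columns as dexamethasone. The numbers of the CT columns match those of the mock titles, but the numbers of the Dx columns match no title. The numbers were therefore not used and no column was tied to a particular sample. The libraries are named here as CT1 to CT3 and Dx4 to Dx6. Nothing says whether the samples of a group came from separate plants or pools, so the p-values measure the spread between these samples, which may be technical.

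Gene names came from the RefSeq annotation of assembly TAIR10.1, in which 28009 of the 28775 loci had a row. No coordinates are given, because the build of the counts is not stated. The share of each named gene's exon sequence that also lies in exons of another gene, on either strand, was computed as the percentage of its 50-base words. Genes that overlap each other therefore count as sharing sequence. This share was over 20% for 9 of 120 named genes (AUR1, CDC20.1, CKX5, IAA3, IAA32, KMD4, LHCB1.3, NAC1 and PCNA2), whose counts are uncertain where reads could be divided between genes or where counting ignored strand.

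Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr by group with its minimum count of 10, and the robust quasi-likelihood test of dexamethasone against mock (glmQLFit and glmQLFTest, two-sided). The p-values were adjusted by the Benjamini-Hochberg method over the 15857 genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. Library-scaled counts (CPM) were computed from the deposited counts on the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. A total of 26 gene lists with 375 members was fixed before the data were examined, and 277 members passed the filter. Lists with at least 3 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 25 lists tested. Camera asks whether a list moved relative to all other genes.

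The genes named were chosen by a rule fixed at the same time. It takes AP2, then the 12 largest positive and 12 largest negative log2 fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap of the groups. It adds each list member past the threshold over all genes or over its list alone, up to the 6 smallest p-values per list, and at most 2 members, as values, of a list with none. Other genes named are said to have been chosen after their values were seen.

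The libraries held 1633571 to 2196781 counts, so 3 counts, the number a count of 0 allows, correspond to 1.38 to 1.88 CPM per library. Intervals and floors cover counting error only. The procedure was tested on simulated counts drawn from the mock means, the library sizes and the estimated dispersions, with 200 of the genes changed. For dexamethasone against mock, over 15541 genes tested, it called 36.4% of 66 genes changed 1.5-fold, 75.8% of 66 genes changed 2-fold and 100% of 60 genes changed 4-fold. Of the 145 genes called, 6.9% were unchanged ones. Both groups were drawn with the same dispersions and few genes were changed, so these shares describe the simulation and need not hold for the data.

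The alternatives planned were DESeq2's size factors, library size scaling, no filter beyond 1 count, a filter of 5 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a minimum fold of 1.5, an adjusted p under 0.1, and leaving out each library. For the lists they were an estimated correlation and fry. A fit with the mean log2 CPM of 8 dawn-phased clock genes (CCA1, LHY, RVE8, RVE1, PRR9, LNK1, LNK2 and CDF1) as a covariate was added after seeing the data.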

Results

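The data are RNA-seq counts from the inflorescence apex of Arabidopsis, with 3 mock libraries and 3 libraries collected 6 to 8 h after dexamethasone had been applied to induce AP2m3. Total counts were 1633571, 2178975 and 2196781 in the mock libraries CT1, CT2 and CT3, and 1833795, 1861235 and 2109788 in the dexamethasone libraries Dx4, Dx5 and Dx6. Between 19608 and 20385 genes had at least 1 count in a library. The dexamethasone libraries resembled each other closely, with Pearson correlations of log2 CPM across genes of 0.974 to 0.975. The mock libraries were more varied, at 0.942 to 0.964, and pairs from different groups gave 0.914 to 0.945. Counts of each pair of libraries differed by more than sampling noise, with a chi-square per gene of 1.27 to 1.35 among dexamethasone pairs and 2.19 to 5.41 among mock pairs, so all 6 were kept as separate samples. The first principal component held 51.9% of the variance and separated the groups. The mock libraries also differed on it, at -39.4, -29.5 and -13.7 for CT1, CT2 and CT3, against 25.8 to 29.1 with dexamethasone. The second, with 19.3%, spread the mock libraries with CT1 and CT3 at its ends. CT3 correlated slightly more closely with Dx4 (0.945) and Dx6 (0.943) than with CT1 (0.942).

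The comparison asks which transcripts change in the apex when AP2 is raised. The AP2 transcript itself (AT4G36920) stood at 64.8 ± 11.8 CPM in mock and 1099 ± 89.3 CPM with dexamethasone, a log2 fold change of 4.08 ± 0.15 (SE; edgeR adjusted p = 2.8e-13), higher in 3 of 3 libraries. Reads of the AP2m3 transgene and of the endogenous gene are not told apart in these counts. Of the genes fixed in lists, 8 of 11 of dormant or starved tissue, 8 of 15 of abscisic acid (ABA), 8 of 13 of photosynthesis and 4 of 14 of floral identity were lower with dexamethasone, and 5 of 14 of touch, wound and jasmonate responses were higher. Camera called these 5 lists and 7 others with its preset correlation and none with an estimated correlation, where the smallest adjusted p of a list was 0.171. In all, 929 genes were higher and 1272 lower out of 15857 tested, of which 213 and 368 changed at least 2-fold.

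The groups did not overlap in 31% of the tested genes, where chance gives 10% for 3 libraries against 3. The counts of genes depended on single libraries. They were 480 higher and 766 lower without CT2, 1816 and 1974 without CT3, 512 and 800 without Dx4, 463 and 668 without Dx5, and 441 and 691 without Dx6. The Wald test of DESeq2 called 549 higher and 815 lower, and a minimum fold of 1.5 left 111 and 177.

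Besides AP2, the 11 genes with the largest positive fold changes, among called genes with a mean of at least 5 CPM and no overlap of the groups, had mock means of 0 to 10.2 CPM. AT5G26290, which encodes a TRAF-like protein, had no count in any mock library and 379 over the dexamethasone libraries (65.1 ± 8.04 CPM), at least 129-fold higher against a floor of 3 counts over the mock group. NAC1, a NAC transcription factor, went from 0.822 ± 0.486 to 22 ± 4.14 CPM (log2 fold change 4.61 ± 0.41; 34.6% of its exon sequence is shared with other genes), and RLP11, a receptor-like protein, from 1.66 ± 1.27 to 27.5 ± 1.32 CPM. PUM11, a Pumilio RNA-binding protein, rose by a log2 fold change of 3.75 ± 0.55, and AT4G16230, a GDSL-type lipase, by 3.59 ± 0.30. The protein phosphatase 2C gene AT3G05640 rose from 8.17 ± 2.21 to 77.9 ± 11.1 CPM. AT1G70270, MLP168, GDU4, IAA32 and BGLU28 rose by log2 fold changes of 3.18, 3.00, 2.90, 2.76 and 2.68, with 46.5% of the exon sequence of IAA32 shared with other genes. Leaving out 1 library moved the log2 fold change of NAC1 to 5.20 (without CT2) and that of RLP11 from 4.11 to 4.80 (without CT1). The edgeR adjusted p-values of these 11 genes lay between 2.9e-10 and 0.00015.

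Among the largest falls, SEN1, a senescence and dark-induced gene, had 83 counts over the mock libraries and 1 over the dexamethasone libraries, a ratio of 81.1 with a counting interval of 14.2 to 3241 (95%, exact binomial). The stress-induced linker histone gene HIS1-3 fell from 28 ± 4.09 to 1.91 ± 1.65 CPM, the dehydrin gene LTI30 from 12.4 ± 4.75 to 0.837 ± 0.512 CPM, and RD29A, a marker of drought and cold responses, from 307 ± 133 to 28.2 ± 6.34 CPM. DRM2, a dormancy-associated gene, fell from 525 ± 171 to 60.2 ± 7.83 CPM. The log2 fold change of HIS1-3 moved from -3.83 to -4.69 without Dx5 and that of LTI30 from -3.72 to -4.33 without Dx6, and the 1 count of SEN1 with dexamethasone was in Dx5. FBA5 and COL5 changed by log2 fold changes of -2.99 ± 0.30 and -2.88 ± 0.26, and AT2G05540 and AT5G21940 by -2.84 ± 0.47 and -2.68 ± 0.30. AT3G15450, LHB1B1 and MYBL2 had log2 fold changes of -4.29 ± 0.58, -3.58 ± 0.71 and -2.72 ± 0.54. Each of these calls was lost when either of 2 libraries was left out, with adjusted p up to 0.0587, 0.0695 and 0.0679, each without Dx5. With limma-voom LHB1B1 and MYBL2 had adjusted p of 0.166 and 0.118, and with the dawn-gene score as a covariate AT5G21940 had adjusted p = 0.122.

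**Figure D1:**
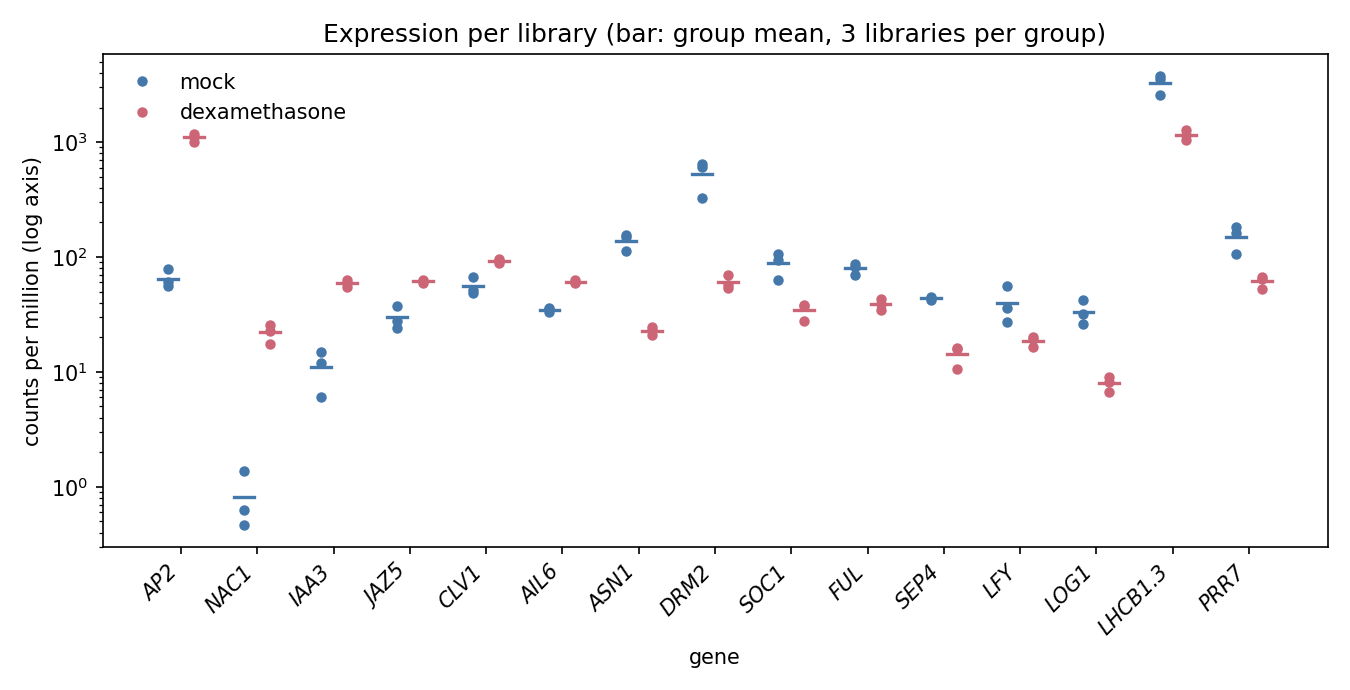
Library-scaled counts (CPM, log axis) of 15 named genes in each of the 3 mock and 3 dexamethasone libraries, with bars at the group means. AP2, NAC1, IAA3, JAZ5, CLV1 and AIL6 were higher and the other 9 lower with dexamethasone, with no overlap between the groups.

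Of 11 measured genes of the list of dormant buds and of starved or senescing tissue, 8 were lower and none higher (9 lower when adjusted over the list alone), with a median log2 fold change of -1.56. ASN1, an asparagine synthetase induced by sugar starvation, fell from 139 ± 22.9 to 22.9 ± 1.85 CPM (log2 fold change -2.60 ± 0.16, edgeR adjusted p = 2.5e-09). The dormancy-associated DRMH1 fell from 490 ± 112 to 173 ± 19.4 CPM, and HB21, a homeobox gene of dormant buds, from 33.1 ± 4.37 to 9.69 ± 0.578 CPM. The list moved lower than other genes by camera (adjusted p = 1.5e-07), and by adjusted p = 0.229 with an estimated correlation. In the ABA list, 8 of 15 measured members were lower and none higher; adjusted over the list alone 9 were lower and 1 higher. NCED3, a rate-limiting enzyme of ABA synthesis, fell from 15.4 ± 8.33 to 2.73 ± 0.573 CPM, ABA1, an earlier enzyme of the pathway, from 80.1 ± 14.3 to 33.6 ± 3.38 CPM, and ABF3, an ABA response factor, from 41.5 ± 15.7 to 10.9 ± 2.17 CPM. CYP707A4, which degrades ABA, also fell, by a log2 fold change of -2.54 ± 0.47. The ABA list had camera adjusted p = 2e-05, and adjusted p = 0.229 with an estimated correlation. Several of these genes varied within the mock group too: DRM2 stood at 642, 604 and 329 CPM in CT1, CT2 and CT3, where 8 dawn-phased clock genes summed to 165, 121 and 73.5 CPM.

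Some regulators of flowering and of floral identity were lower with dexamethasone, 6 of 13 and 4 of 14 measured members. FUL, a MADS-box gene that promotes the end of flowering and represses AP2-like genes, fell from 79.5 ± 8.54 to 38.7 ± 4.24 CPM (log2 fold change -1.04 ± 0.15, edgeR adjusted p = 7.6e-05). SOC1, a MADS-box promoter of flowering, fell from 87.9 ± 22.6 to 34.6 ± 5.85 CPM, and its relative AGL42 by a log2 fold change of -0.86 ± 0.19. None of the flowering regulators was higher, and 7 were lower when adjusted over the list alone (camera adjusted p = 0.00063; adjusted p = 0.307 with an estimated correlation, and 0.181 with the dawn-gene score as a covariate, where the mean log2 change was -0.21 against -0.62). The calls of SPL4, TFL1 and AGL71 were each lost without 4 or 5 of the libraries in turn, with adjusted p up to 0.0985 without Dx4, 0.212 without CT1 and 0.175 without Dx5, and the log2 fold change of TFL1 went from -1.59 to -0.88 without CT1. In the floral identity list 4 of 14 measured members were lower and none higher, and 5 were lower and 1 higher when adjusted over the list alone. This list was also fixed as markers of flower tissue left on the apex. Whether the groups differed in such tissue was not tested. SEP4 fell from 43.5 ± 1.4 to 14.3 ± 3.09 CPM, SEP3 from 204 ± 39.8 to 105 ± 5.35 CPM, AP1 from 222 ± 28.2 to 117 ± 16.9 CPM, and LFY, which sets floral meristem fate, from 40 ± 14.8 to 18.6 ± 1.88 CPM. The list had camera adjusted p = 0.0145, and adjusted p = 0.291 with an estimated correlation. With the dawn-gene score as a covariate LFY lost its call (log2 fold change -0.43, adjusted p = 0.3), as did SPL4, TFL1 and AGL71. AP3 and CRC passed the threshold over the list alone, with log2 fold changes of 0.32 ± 0.12 and -0.42 ± 0.16 and adjusted p of 0.0911 and 0.103 over all genes by edgeR.

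Among the genes with a miR172 site, AP2 was higher and its relative TOE2 lower, by a log2 fold change of -0.59 ± 0.17. TOE1 and TOE3 passed over the list alone, at -1.05 ± 0.38 and -0.64 ± 0.31. Because of AP2 the mean of the 4 measured members was 0.49 while their median was -0.56, and camera gave no call (adjusted p = 0.631). The TOE2 call was lost without 4 of the libraries in turn (adjusted p up to 0.138, without CT2). The 8 precursors of miR172 and miR156 had at most 3 counts in any library and were not tested.

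Few core meristem regulators were called. Of 18 measured members of the stem cell and meristem list 1 rose and 1 fell, and 1 rose when adjusted over the list alone (camera adjusted p = 0.467). A further 5 members were not measured. The mixed fry test, which counts changes in either direction, gave the list adjusted p = 0.00232, so smaller changes may be present. CLV1, the receptor kinase that limits the stem cell domain, rose from 56.2 ± 9.88 to 93 ± 3.45 CPM (log2 fold change 0.72 ± 0.14, edgeR adjusted p = 0.00179). BOP2 had a log2 fold change of -0.70 ± 0.22, a call lost without 5 of the libraries in turn (adjusted p up to 0.234, without Dx5). In the list of lateral organ polarity and growth 4 of 17 measured members rose and none fell, also over the list alone. AIL6, an AINTEGUMENTA-like growth regulator, rose from 34.8 ± 1.38 to 60.8 ± 2.09 CPM, and PHV, an HD-ZIP III gene of the upper side of organs, from 107 ± 5.25 to 169 ± 6.5 CPM. This list had camera adjusted p = 0.0108, adjusted p = 0.224 with an estimated correlation, and adjusted p = 0.0921 with the dawn-gene score as a covariate, where its mean log2 change was 0.20 against 0.25. The calls of ATHB-15 and KAN2 were each lost without 5 of the libraries in turn (adjusted p up to 0.149 without Dx4 and 0.226 without CT2), and with the dawn-gene score as a covariate (0.295 and 0.428).

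A few replication and mitosis genes were higher by small amounts. Of 12 measured S-phase genes 4 were higher and none lower, also over the list alone, with a mean log2 change of 0.50 (camera adjusted p = 0.00031; adjusted p = 0.36 with an estimated correlation, and 0.758 with the dawn-gene score as a covariate, where the mean was 0.063). PCNA1 and PCNA2, subunits of the replication clamp, had log2 fold changes of 0.51 ± 0.15 and 0.47 ± 0.13, with TSO2 at 0.43 ± 0.14 and CDC45 at 0.62 ± 0.21. Each of these 4 calls was lost without at least 4 of the libraries in turn, with adjusted p up to 0.18, 0.137, 0.269 and 0.197, the first 3 without CT2 and CDC45 without Dx5, and each was lost with the dawn-gene score as a covariate. Of 17 measured G2 and M phase genes 2 were higher and none lower, and 3 were higher over the list alone. The list had camera adjusted p = 0.0164, adjusted p = 0.229 with an estimated correlation, and adjusted p = 0.0655 without CT2. AUR1 and CDKB1;2 had log2 fold changes of 0.57 ± 0.15 and 0.64 ± 0.18. Both calls were lost without Dx5 or Dx6, and that of CDKB1;2 also without CT2, with adjusted p up to 0.0851 and 0.115. PCNA2 and AUR1 share 23.3% and 22.5% of their exon sequence with other genes. Of the 10 D-type cyclins and KRP inhibitors, CYCD3;2 fell from 204 ± 36.5 to 123 ± 13.2 CPM and CYCD3;3 rose from 125 ± 5.6 to 185 ± 5.48 CPM, and 2 were higher and 2 lower over the list alone (camera adjusted p = 0.378).

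Cytokinin genes changed in both directions. LOG1, a cytokinin-activating enzyme, fell from 33.5 ± 8.33 to 8 ± 1.23 CPM (log2 fold change -2.08 ± 0.24, edgeR adjusted p = 8.5e-06). LOG5 had a log2 fold change of -0.69 ± 0.16, a call lost without Dx4 (adjusted p = 0.061). Thus 2 of 4 measured synthesis and activation genes were lower, and 3 over the list alone (camera adjusted p = 0.00092; adjusted p = 0.224 with an estimated correlation). In the list of cytokinin degradation and signalling repression 2 of 7 measured members were higher and 4 lower, also over the list alone, with no call by camera (adjusted p = 0.35). The cytokinin oxidase gene CKX7 fell by a log2 fold change of -1.19 ± 0.18 and CKX3 rose by 1.38 ± 0.30. KMD1 and KMD4, F-box genes whose products remove type-B response regulators, changed by -2.34 ± 0.39 and -1.46 ± 0.22. The calls of CKX5 (higher) and KMD2 (lower) were lost without 3 and 4 of the libraries in turn, both with adjusted p highest without CT2 (0.141 and 0.0851), and with the DESeq2 Wald test, and 24.6% of the CKX5 exon sequence is shared with other genes. Nearly all of the KMD4 exon sequence (96.8%) also lies in exons of other annotated genes, on either strand. Its counts are uncertain where reads could be divided between genes or where counting ignored strand. Of 11 measured receptors, phosphotransfer proteins and type-B regulators 2 were lower, and 3 were lower and 1 higher over the list alone (camera adjusted p = 0.249). These 2, ARR1 and ARR2, lost their calls without 3 and 5 of the libraries in turn, both of them without CT2, Dx4 or Dx6, and with the DESeq2 Wald test. Their adjusted p was highest without Dx6 (0.172) and without Dx5 (0.11). Of 8 measured type-A regulators 1 was higher and 2 lower, and 1 and 3 over the list alone (camera adjusted p = 0.603). ARR9 fell from 19 ± 5.91 to 7.95 ± 1.03 CPM. The calls of ARR15 (higher) and ARR7 (lower) were each lost without 5 of the libraries in turn, with adjusted p up to 0.18 without CT2 and 0.266 without Dx5. With the dawn-gene score as a covariate LOG5, CKX3, CKX5, KMD2, ARR2, ARR9, ARR15 and ARR7 lost their calls (adjusted p = 0.11, 0.069, 0.217, 0.469, 0.32, 0.216, 0.262 and 0.478).

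Of 9 measured early auxin response genes 3 rose and none fell, also over the list alone. IAA3 went from 11 ± 4.56 to 59.2 ± 4.09 CPM (log2 fold change 2.46 ± 0.22, edgeR adjusted p = 2.5e-07) with 36.6% of its exon sequence shared with other genes, and IAA19 from 3.86 ± 2.09 to 14.3 ± 4.12 CPM. The third, IAA2, stood at 8.11 ± 4.42 CPM in mock and 16.8 ± 3.64 CPM with dexamethasone, a call lost without 4 of the libraries in turn (adjusted p up to 0.177, without Dx6). IAA19 lost its call with the dawn-gene score as a covariate (log2 fold change 0.93, adjusted p = 0.179). The list's mean log2 change was 0.49 and its median -0.01, with no call by camera (adjusted p = 0.378). Of 14 measured auxin synthesis and transport genes TAR2 rose, from 45.8 ± 2.64 to 73.3 ± 4.86 CPM, and none fell, also over the list alone (camera adjusted p = 0.603). In the gibberellin list 1 of 11 measured members rose and 3 fell, and 1 and 5 over the list alone. GA2OX1 and GA2OX2, which inactivate gibberellin, fell from 16.5 ± 5.99 to 3.29 ± 1.12 CPM and from 24.3 ± 3.32 to 10.5 ± 2.15 CPM, while the DELLA repressor gene GAI rose from 54.8 ± 3.9 to 92.5 ± 3.71 CPM. RGL2, another DELLA gene, had a log2 fold change of -0.66 ± 0.15 (adjusted p = 0.00622), a call lost without Dx5 (0.0516). The list had camera adjusted p = 0.0288, adjusted p = 0.307 with an estimated correlation and adjusted p = 0.141 without CT3.

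Photosynthetic genes, fixed as markers of green tissue, were lower with dexamethasone. Of 13 measured members 8 fell and 1 rose, and 10 and 1 over the list alone (camera adjusted p = 1.6e-05; adjusted p = 0.171 with an estimated correlation). LHCB1.3 and LHCB3, antenna proteins of photosystem II, changed by log2 fold changes of -1.50 ± 0.14 and -1.49 ± 0.15, RCA, which activates Rubisco, by -0.92 ± 0.14 and the Rubisco subunit gene RBCS1A by -0.69 ± 0.11. GLK1, a regulator of chloroplast development that the naming rule did not take and that was chosen after its values were seen, was the member that rose (0.62 ± 0.17), while GLK2 fell (-1.73 ± 0.39). LHCB1.3 shares 22% of its exon sequence with other genes, the most with AT1G29920, and its own counts are uncertain to that degree.

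Clock genes differed between the groups and within the mock group. Of 13 measured members 1 rose and 5 fell, and 1 and 10 over the list alone (camera adjusted p = 0.00029; adjusted p = 0.291 with an estimated correlation). PRR7 fell from 150 ± 38.6 to 61.5 ± 8.01 CPM and LNK1 from 50.5 ± 11.5 to 21.7 ± 7.13 CPM. The calls of GI (-0.67 ± 0.16), ELF4 (0.53 ± 0.14), FKF1 (-0.51 ± 0.15) and GRP7 (-0.42 ± 0.12) were each lost without at least 3 of the libraries in turn, with adjusted p up to 0.0859 without Dx6, 0.0967 without Dx4, 0.164 without CT2 and 0.199 without Dx5. With the dawn-gene score as a covariate ELF4 and FKF1 had adjusted p of 0.0509 and 0.292. The 8 dawn-phased members summed to 165, 121 and 73.5 CPM in CT1, CT2 and CT3 and to 61.9, 53.5 and 41.4 CPM in Dx4, Dx5 and Dx6.

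Of 14 measured touch, wound and jasmonate genes 5 were higher and none lower, and 6 were higher over the list alone (camera adjusted p = 0.00085; adjusted p = 0.218 with an estimated correlation). JAZ5 and JAZ1, repressors induced by jasmonate, rose from 29.9 ± 6.87 to 61.8 ± 2.15 CPM and from 40.2 ± 8.07 to 67.5 ± 7.58 CPM, and the calmodulin-like genes TCH2 and TCH3 by log2 fold changes of 0.89 ± 0.15 and 1.21 ± 0.26. OPR3, a jasmonate synthesis gene, had a log2 fold change of 0.55 ± 0.13, a call lost without CT2 (adjusted p = 0.0565) or Dx5 (0.0642). TCH3 lost its call with the dawn-gene score as a covariate (log2 fold change 0.48, adjusted p = 0.247).

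Markers of other tissues were called in small numbers, where 13.9% of all tested genes were called. This does not show that tissue shares were equal. None of 13 measured anther and tapetum markers was called (camera adjusted p = 0.378, and 0.0418 without Dx6). Log2 fold changes were 0.64 ± 0.32 for TPD1 and 0.48 ± 0.30 for A9. The 13 markers summed to between 382 and 1137 CPM per library, so changes could be missed. Of 10 epidermal markers SHN1, a regulator of cuticle formation, rose from 50.7 ± 10.1 to 113 ± 3.11 CPM and CUT1, a wax synthesis gene, fell from 278 ± 40.7 to 179 ± 9.48 CPM, also over the list alone (camera adjusted p = 0.603). Of 10 measured vascular markers 2 fell, also over the list alone (camera adjusted p = 0.402, and 0.00046 with the dawn-gene score as a covariate, where the mean log2 change was -0.75 against -0.13). These were the phloem genes SUC2 and SEOR1, at -0.72 ± 0.17 and -0.76 ± 0.20, with calls lost without 2 and 3 of the libraries in turn (adjusted p up to 0.0782 and 0.115, both without Dx5). None of 5 CIN-type TCP genes (camera adjusted p = 0.603) or 4 heat shock genes (0.779) was called, over all genes or over the list alone. Log2 fold changes were -0.44 ± 0.16 for TCP10, -0.13 ± 0.18 for TCP4, -0.21 ± 0.32 for HSFB2A and -0.14 ± 0.24 for HSP101. With the dawn-gene score as a covariate TCP10 passed the threshold (adjusted p = 0.00169).

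**Figure D2:**
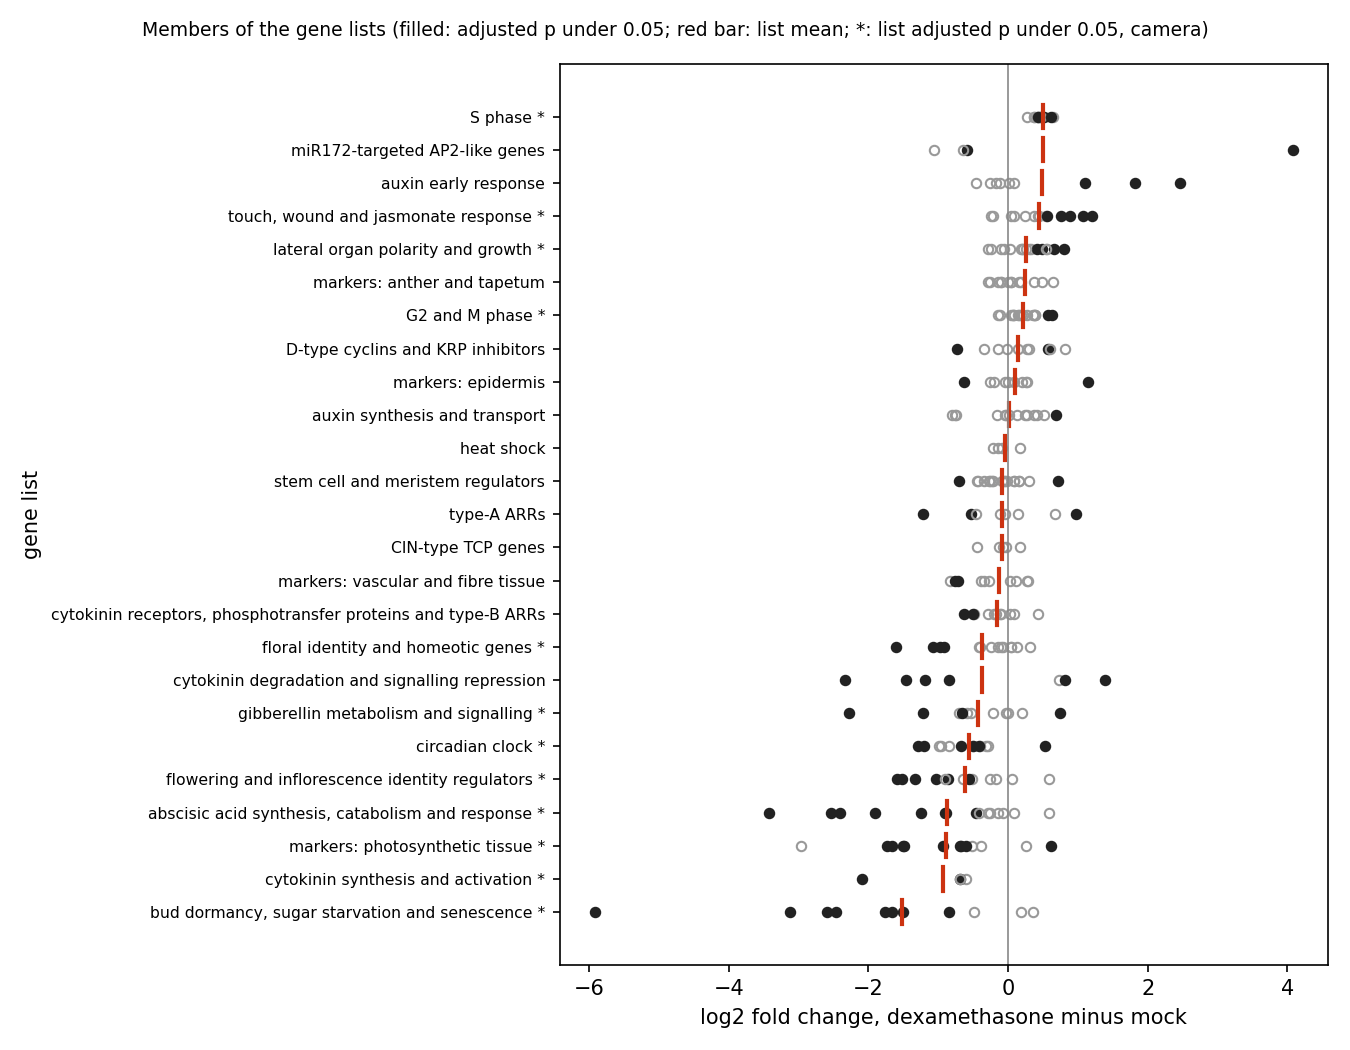
Log2 fold change (dexamethasone minus mock) of each measured member of the 25 gene lists tested, with filled points for genes past the threshold over all genes, red bars at list means and asterisks for the 12 lists called by camera. The list means ran from -1.52 for the dormancy and starvation list to 0.50 for the S-phase list.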

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

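The AP2 log2 fold change stayed between 3.98 and 4.23 in each alternative planned, past the threshold in all of them. The counts of genes stayed within 1.5 times of 929 higher and 1272 lower with DESeq2's size factors, with library size scaling, without the filter, with limma-voom, at an adjusted p under 0.1 and without CT1. The planned filter of 5 CPM kept 15894 genes and so was no stricter than the 15857 of filterByExpr. The Wald test of DESeq2 called 549 and 815, of which 544 and 807 were among the edgeR calls, and a minimum fold of 1.5 left 111 and 177; the cause of the lower DESeq2 count was not tested, while the minimum fold removes small changes by construction. Leaving out 1 library gave 441 to 1816 genes higher and 668 to 1974 lower. The highest counts came without CT3 and the lowest without Dx5 or Dx6, and the fewer samples leave fewer residual degrees of freedom. With the dawn-gene covariate, added after the data were seen, 891 were higher and 1169 lower, of which only 501 and 707 were among the main calls. Library size scaling shifted the median log2 fold change by 0.02.

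Camera called 12 lists with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.171. The estimate was below the preset 0.01 for the photosynthesis (-0.0689), touch (-0.00882) and lateral organ (-0.0087) lists. A higher correlation therefore did not remove these calls, and the estimated setting also has only the residual degrees of freedom of 6 libraries. For the other lists called the estimate was above 0.01, up to 0.527 for the S-phase list. The directional fry test of limma called 15, not the S-phase list (adjusted p = 0.0866), and its mixed test 20. Neither compares a list with other genes. The list of genes with a miR172 site, lower by camera without a call, was called higher by fry (mean log2 change 0.49, adjusted p = 0.00502), since AP2 dominates its mean. AP2 is the gene induced here, so this call follows from the treatment itself. Directional fry also called the lists of early auxin response (adjusted p = 0.00502), cytokinin degradation (0.0323) and cytokinin receptors (0.00921), which camera did not call. TCP4, not called, had log2 fold changes from -0.35 without CT1 to 0.018 without CT2, the setting in which its sign changed. Of 99 named genes past the threshold beside AP2, 67 stayed past it without each library in turn, 80 with the DESeq2 Wald test, 92 with limma-voom, 43 with a minimum fold of 1.5 and 74 with the dawn-gene covariate, and none changed direction in any planned setting. No paired analysis was possible because the columns carry no replicate numbers shared between the groups. In the simulation, with 200 changed genes and the same dispersions in both groups, 36.4% of 1.5-fold changes were called. In these data 2201 genes were called. The spread between libraries beyond counting noise (edgeR's common biological coefficient of variation) was 14.9% in mock and 4.81% with dexamethasone. The simulated share therefore does not measure the power here, and genes not called may include small changes.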

Other observations

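The grouping of genes by product name, and all tests here except the splits of the libraries, were chosen after the results were seen, as were the bounds those tests were held to. Among 214 groups of at least 10 tested genes that share a product name in the annotation, 7 were enriched among the genes higher with dexamethasone and 3 among those lower (one-sided Fisher's exact tests, adjusted over 428 tests). Of the 6 not described further, leucine-rich repeat proteins went from 13 higher to 2 without CT2 and 3 with the dawn-gene covariate, aspartyl proteases from 8 higher to 3 without CT2, Dx4 or Dx6, and plastid transcriptionally active proteins from 6 lower to 1 without Dx5. Sec14p-like proteins went from 7 higher to 4 without Dx4 or Dx6, pectin lyase-like proteins from 8 higher to 4 without Dx6, and rhodanese-like proteins from 5 lower to 2 without Dx5. The histone superfamily, here only the genes with that product name, stood first. The linker histone gene HIS1-3, which fell (log2 fold change -3.83), has another product name and is not in this group. Of 27 tested members 14 were higher and none lower (adjusted p = 2.1e-08), with a median log2 fold change of 0.46, for example AT5G59690 from 419 to 628 CPM and AT5G10400 from 179 to 288 CPM. The number higher was 7 without CT2, 7 without Dx4, 9 without Dx5, 6 without Dx6, 19 without CT1 and 19 with the dawn-gene covariate (median 0.65), and none was lower in any of these. Histone genes are close copies, and whether reads were divided among them was not tested. Arabinogalactan proteins, which are secreted to the cell wall, had 6 of 15 higher and 1 lower (adjusted p = 0.0136), and 3 higher without Dx4 or Dx5. Among 11 xyloglucan endotransglucosylase/hydrolases, which remodel wall polymers, 5 were higher (adjusted p = 0.0167) and 4 lower, with a negative median of -0.31 and with AT4G03210 going from 1429 to 2720 CPM and AT4G30270 from 17.3 to 4.12 CPM. The number higher in this group was 3 without CT2 or Dx4, the number lower was 2 without Dx5, and with the dawn-gene covariate 5 were higher and 2 lower, with a positive median of 0.19. MATE efflux transporters fell, with 12 of 22 lower and none higher (adjusted p = 4.4e-06), among them AT1G47530 from 115 to 46.5 CPM. Of these, 6 were lower without Dx5, 8 without CT2 and 7 without Dx6, and with the dawn-gene covariate 6 were lower and 1 higher.

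AT5G26290 had 0 counts over the mock libraries and 379 with dexamethasone, while the 3 nearest genes of the count table on each side had at most 1 count over the mock libraries and 4 over the dexamethasone libraries. Only 2.28% of its exon sequence is shared with another gene, the most with AT5G26260. The 13 measured anther and tapetum markers summed to 382 CPM in CT1, 1012 in CT2, 1004 in CT3, 1137 in Dx4, 813 in Dx5 and 597 in Dx6, a spread that does not follow the groups.

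The number of genes changed is the first pattern weighed. The real grouping gave 2201 genes and was the only 1 of the 10 splits of the 6 libraries into 3 and 3 with as many, the highest other being 0, but 10 splits are too few for a share under 0.05. Each other split also puts mock and dexamethasone libraries in both groups, which widens the spread within them. Few calls would be found there whatever made the groups differ. With the dawn score in the fit 54.9% of the called genes were still called in the same direction, while 1348 genes followed the score. This does not decide whether a trend in the dawn-phased clock genes is the source. Each dexamethasone library scored lower (mean log2 CPM 1.71 to 2.04) than each mock library (2.06 to 3.52). Only 3 of the 8 dawn genes stood above the floor of 3 counts in each dexamethasone library, so the score may understate the difference between the groups. An effect of dexamethasone apart from AP2m3 stays open, as no treated plants without the transgene were analysed here.

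The fall of dormancy, starvation and ABA genes is the second. With the dawn score in the fit 11 of the 16 called members were still lower. The median log2 fold change of the 16 went from -1.83 to -1.47. These values do not decide on the trend in the dawn-phased clock genes, for the reasons given above. The 16 were also chosen because they fell in these same libraries. DRM1 lost its call as its log2 fold change shrank from -0.84 ± 0.23 to -0.22 ± 0.18, and DIN10 (-1.66 ± 0.24 to -1.43 ± 0.48), ABI1, ABI5 and NAP lost theirs with both smaller folds and larger errors. A later hour of collection than that of any mock library may still contribute and cannot be told apart from the treatment. Only 3 of the 8 dawn genes stood above the floor of 3 counts in each dexamethasone library. Of the 8, 3 were lower in each dexamethasone library than in each mock library. A later hour would give this only while dawn-phased transcripts are falling, and the labels do not state the hour of collection. The induction of AP2m3 stays open beside a later hour, untested.

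The fall of photosynthetic genes is the third. One candidate explanation is less green tissue in the dexamethasone samples, which would lower the markers alike. Their log2 fold changes differed by more than their errors (Cochran's Q = 173 over 13 markers, where equal changes give about its 12 degrees of freedom), and GLK1 rose, but 8 of the 13 fell. Meristem cells may hold part of these transcripts, so unequal falls do not exclude a smaller share of green tissue, and this cannot be told apart from lower expression per cell.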
